A study of Mus musculus with 8 samples.

How the data were processed

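Bulk RNA sequencing of total RNA had been done on thymic ILC2 cells of plck-Id1 transgenic C57BL/6 mice, transduced with MIGR1 retrovirus carrying GFP alone or GFP with E47-ER and treated with 4-hydroxytamoxifen for 4 or 16 h. The deposited values are raw counts, 1 whole number per Ensembl gene and library, as deposited by the authors with no normalization. Per the labels, the genome build was mm10 and DESeq2 was used, with no version and no stated role. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. The table held 50686 genes and 8 libraries, all of them used, in 4 groups of 2. Of the gene IDs, 50376 matched GENCODE release M21 (GRCm38), which gave symbols, coordinates and transcript lengths, and 310 had no symbol. There were 68 symbols on more than 1 ID, so genes were followed by ID. Library totals ran from 8813782 to 18677675 counts, ribosomal RNA genes took 0.428 to 1.16% and mitochondrial genes 1.23 to 1.71% of them.

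Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10, which left 13644, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 8 libraries and gave 4 comparisons: E47-ER against GFP at 4 h and at 16 h, the difference between these effects, and 16 h against 4 h in GFP cells. Two-sided p values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM, counts scaled to library size, with the SD of 2 libraries. The 4 h and 16 h comparisons share no library, while the time comparison in GFP cells shares its libraries with both. Without a library, the remaining library of its group was assumed to vary like the other groups.

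Before the data were examined, 36 gene lists were fixed, of which 33 had at least 5 members among the tested genes. Lists of B cell markers (3 members tested), erythroid markers (2) and construct genes (3) were too small to test. Lists were tested in limma 3.58.1 with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list moves in 1 direction and does not compare it with other genes. Many lists share members: 26 of the 29 genes of the E protein target list, for example, stand in another list. The named genes followed a rule fixed before the data were examined. Tcf3, Esr1 and Id1 were always named. Each main comparison gave up to 10 genes per direction with the largest log2 fold change among called genes with a log2 CPM of 3 or more, both E47-ER libraries on the same side of both GFP libraries, and no predicted gene, pseudogene or variable segment. Up to 4 called members per list were added by smallest adjusted p, with Gata3, Rora, Il1rl1, Il17rb, Icos, Klrg1, Il7r, Il2ra, Il5, Il13, Il4, Areg, Id2, Id3, Bcl11b, Tcf7, Ptcra and Rag1. The difference between times gave 8 genes per direction by smallest p and the GFP time comparison 5. Where under 5 genes were called in a direction, the 5 with the smallest p were given as values. The same rule was repeated without replicate 2 of GFP at 16 h, a repeat chosen after that library was seen to stand apart.

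The procedure was tested on simulated data, counts with 100 genes changed at each fold in 5 draws. Apart from the changed genes, every library was drawn independently from the same mean and dispersion per gene. No simulated library therefore stood apart by transcript length. With all 8 libraries, 51% of genes changed 2-fold at 4 h and 51.6% at 16 h were recovered, and 91.4 and 89.4% of those changed 4-fold, with 6.68 and 6.62% false calls, above the nominal 5%. When replicate 2 of GFP at 16 h was left out, recovery of 2-fold changes was 73 and 68.6%, with 11.2 and 9.28% false calls. Alternatives were DESeq2 1.42.0, RLE scaling, library totals only, no filter on low counts, a minimum count of 30, no robust dispersion, other thresholds, only the 4 libraries of a time, a replicate block within or across times, leaving out each library in turn, and limma voom with quality weights, which was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.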

Results

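Bulk RNA sequencing was carried out on group 2 innate lymphoid cells (ILC2), lymphocytes that secrete type 2 cytokines, from the thymus of C57BL/6 mice with the plck-Id1 transgene. Id1 encodes an inhibitor of E proteins, the transcription factor family to which E47, a product of Tcf3, belongs. The cells carried the MIGR1 retroviral vector with GFP alone or with GFP and E47-ER, in which E47 is fused to the estrogen receptor so that 4-hydroxytamoxifen releases its activity. GFP-positive cells were expanded with IL-7, IL-25 and IL-33 and given 4-hydroxytamoxifen for 4 or 16 h. The comparisons asked which genes differed between E47-ER and GFP cells at each time. No E47-ER library without 4-hydroxytamoxifen was included. A difference present before the drug was given therefore cannot be told apart from a response to E47 activity. The 4 groups held 2 libraries each. Total counts were 15459513 and 18677675 in GFP cells and 15212699 and 13761761 in E47-ER cells at 4 h. At 16 h they were 14510001 and 8813782 in GFP cells and 14518308 and 16982013 in E47-ER cells. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

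Replicate 2 of GFP at 16 h stood apart from the other 7 libraries. Its mean Pearson correlation of log2 CPM across genes with the other libraries was 0.954, against 0.980 to 0.983 for the others, and its trimmed-mean scaling factor was 0.854, against 1.01 to 1.03. The first principal component held 51.5% of the variance and placed this library at 78.4, with the others between -26.8 and 1.83. The median absolute log2 difference between replicates was 0.457 for GFP at 16 h, against 0.151 for GFP at 4 h, 0.133 for E47-ER at 4 h and 0.126 for E47-ER at 16 h. Short transcripts were over-represented in this library. Among genes with transcripts under 1017 bases, the median log2 difference of this library from the other GFP libraries was 0.82. Among genes with transcripts above 6473 bases it was -0.42. Counts of the comparisons are therefore given with all 8 libraries and again without this library, a choice of emphasis made after it was seen. Without it, the lone GFP library at 16 h was assumed to vary like the other groups.

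**Figure D1:**
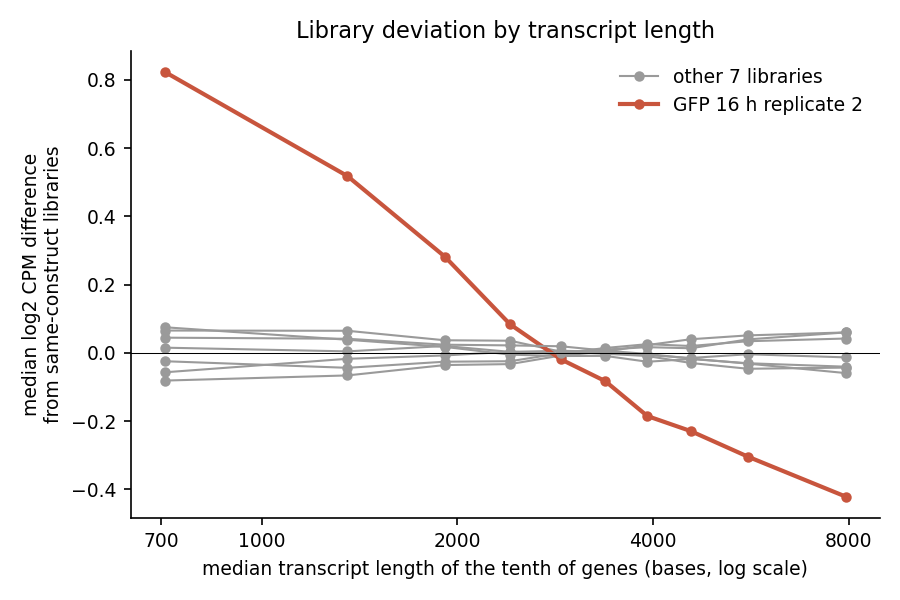
Median difference in log2 CPM of each library from the other libraries of its construct (y axis) for equal-sized bins of genes ordered by transcript length (x axis, median length in bases, log scale). Replicate 2 of GFP at 16 h was left out of the reference of the other GFP libraries. Replicate 2 of GFP at 16 h (red) goes from 0.82 in the shortest bin to -0.42 in the longest, while the other 7 libraries (grey) lie near 0.

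The construct was seen in the labelled libraries. Esr1 (ENSMUSG00000019768; chromosome 10, 4611593 to 5005614, GRCm38), the estrogen receptor gene, stood at 0.264 ± 0.0741 CPM (SD, n = 2) in GFP cells at 4 h and 49.1 ± 4.94 in E47-ER cells, a ratio of 186. At 16 h it stood at 0.735 ± 0.279 and 49.1 ± 7.55 CPM (n = 2 each), a ratio of 66.9. Reads of Esr1 and Tcf3 cannot be divided between the construct and the cells' own genes. Tcf3 (ENSMUSG00000020167; chromosome 10, 80409514 to 80433647) stood at 80.4 ± 1.39 CPM in GFP cells and 157 ± 8.82 in E47-ER cells at 4 h (log2 fold change 0.96, SE 0.158, adjusted p = 0.0697 by edgeR's quasi-likelihood test). At 16 h Tcf3 was higher with E47-ER, at 158 ± 16.8 against 77.6 ± 14.1 CPM (log2 fold change 1.02, SE 0.159, adjusted p = 0.0238). Id1 (ENSMUSG00000042745; chromosome 2, 152736251 to 152737410), whose reads include those of the transgene where they match, was 2.09 times as high with E47-ER at 4 h (adjusted p = 0.531) and 3.4 times at 16 h (adjusted p = 0.0551). Without replicate 2 of GFP at 16 h, Tcf3 and Id1 passed the threshold at both times, Id1 with adjusted p = 0.0327 at 4 h and 0.0253 at 16 h.

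**Figure D2:**
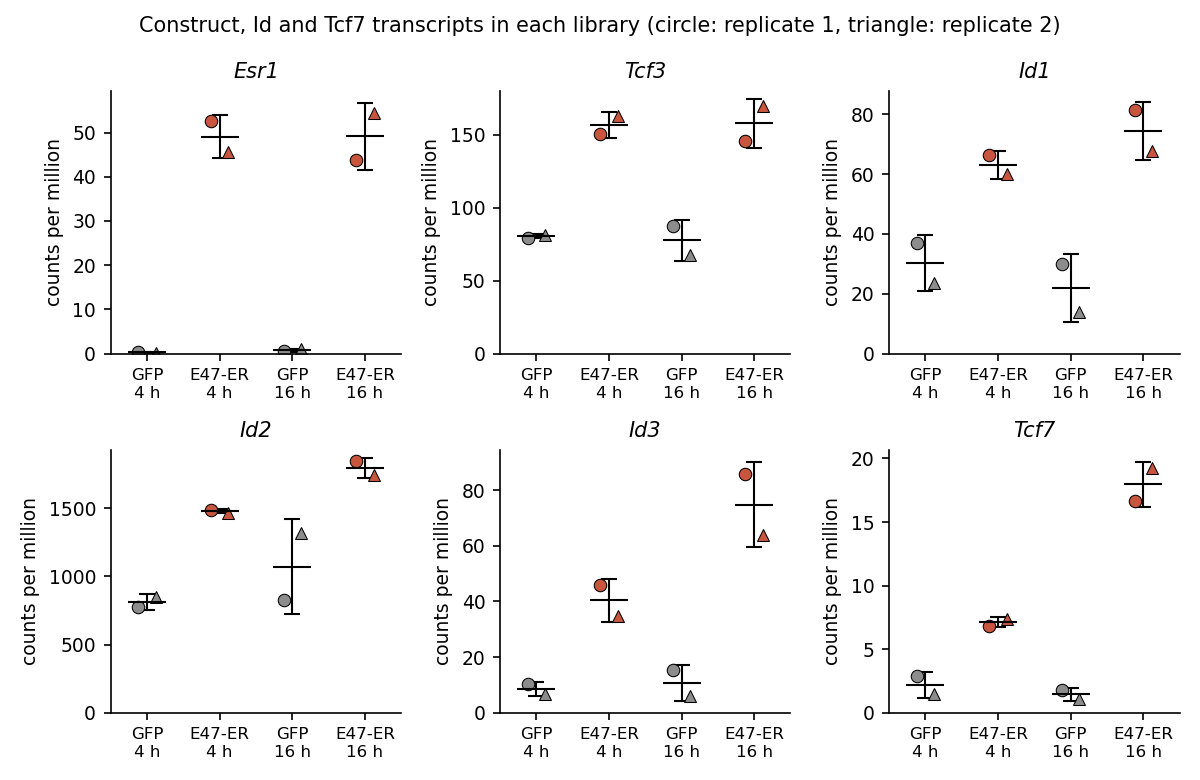
CPM per library (y axis) of Esr1, Tcf3, Id1, Id2, Id3 and Tcf7 in GFP and E47-ER cells at 4 and 16 h (x axis); circles are replicate 1, triangles replicate 2, lines the group mean and whiskers the SD (n = 2). Esr1 stays under 1 CPM in the GFP libraries and lies between 43.8 and 54.5 CPM in the E47-ER libraries.

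At 4 h, 37 genes were higher and 2 were lower in E47-ER than in GFP cells among 13644 tested (adjusted p under 0.05). The higher genes included Esr1, whose reads include the construct. Ctsl, the lysosomal protease cathepsin L (ENSMUSG00000021477; chromosome 13, 64359337 to 64370890), went from 30.9 ± 7.70 to 261 ± 0.716 CPM (SD, n = 2; log2 fold change 3.08, SE 0.333, adjusted p = 0.0171). Its neighbour Cdk20, a cyclin-dependent kinase (ENSMUSG00000021483; 64432314 to 64441773), went from 1.56 ± 0.332 to 14.3 ± 0.561 CPM (3.17, SE 0.21, adjusted p = 0.00205). Cbfa2t3, a corepressor that binds E proteins (ENSMUSG00000006362; chromosome 8, 122625141 to 122699109), went from 0.0844 ± 0.03 to 2.49 ± 0.35 CPM (4.72, SE 0.443, adjusted p = 0.0104). Its GFP level lies near the 0.0863 CPM that 3 counts over the GFP group would give, so the size of its rise is uncertain. Snai3, a Snail family zinc finger gene on the same chromosome (ENSMUSG00000006587; 122454208 to 122460733), went from 2.26 to 10.8 CPM (2.26, SE 0.191, adjusted p = 0.00551). Gal, the gene of the neuropeptide galanin (ENSMUSG00000024907; chromosome 19, 3409915 to 3414544), had 0 counts in both GFP libraries at 4 h and 1.83 ± 0.87 CPM in E47-ER cells (adjusted p = 0.0429). That was at least 21.2-fold higher than the 0.0863 CPM that 3 counts over the GFP group would give. The costimulatory receptor gene Cd27 rose 5-fold (2.41, adjusted p = 0.033), with reads that may be shared with Vamp1, which overlaps it. Also higher were Lrrc32, whose product binds latent TGF-beta (1.88, adjusted p = 0.0171), and Spsb1 (2.09, adjusted p = 0.0104). So were Crispld2 (2.31, adjusted p = 0.0226), the semaphorin gene Sema6d (2.16, adjusted p = 0.0429) and the GD3 synthase gene St8sia1 (2.12, adjusted p = 0.014). The 2 lower genes were Nlrp3, an inflammasome sensor (log2 fold change -1.098, SE 0.147), and Zbtb32, a transcriptional repressor (-1.08, SE 0.144), each with adjusted p = 0.033. Among genes with a fall that did not pass, Ak4 had -0.75 (adjusted p = 0.0697), Pou2f2 -0.99 (0.0786) and Scn7a -0.85 (0.15).

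Among the 33 gene lists fixed before the data were examined and large enough to test, 14 were called at 4 h by camera with a preset inter-gene correlation of 0.01, 7 higher and 7 lower. The E protein and Id network had 1 of 8 members higher over all genes tested (Cbfa2t3) and 6 higher and 1 lower adjusted over the list alone (median log2 fold change 1.01, adjusted p = 8.92e-15, and adjusted p = 0.0379 with an estimated correlation). This list holds Tcf3, whose reads include the construct, and Id1, whose reads include the transgene where they match. It was not tested without these genes, so its call is in part fixed by the construct. It also holds the inhibitor genes Id2 (0.86, adjusted p = 0.332) and Id3 (2.24, adjusted p = 0.0842). T lineage genes had 3 of 27 members higher: Trbc1 (1.94, adjusted p = 0.033), Trbc2 (1.53, SE 0.175, 20.7 to 59.8 CPM, adjusted p = 0.0201) and Cd27. Adjusted over the list alone 7 were higher and 1 lower (median 0.0825, adjusted p = 1.61e-06, and adjusted p = 0.0721 with an estimated correlation). Of the ILC3 and type 17 genes, 1 of 15, the lymphotoxin gene Ltb, was higher (1.15, SE 0.164, 21.2 to 46.9 CPM, adjusted p = 0.0429), and 3 adjusted over the list alone (median 0.50, adjusted p = 2.09e-06, and adjusted p = 0.151 with an estimated correlation).

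ILC2 identity genes had 0 of 38 members called over all genes at 4 h and 5 higher adjusted over the list alone (median 0.167, adjusted p = 0.000238, and adjusted p = 0.0721 with an estimated correlation). Among them Rora, a transcription factor needed for ILC2 development, had a log2 fold change of 0.85 (adjusted p = 0.0608), while Gata3 had -0.18, the IL-33 receptor gene Il1rl1 0.00 and the IL-25 receptor gene Il17rb 0.44 (adjusted p of 0.88 or more). E protein targets of B and T progenitors had 0 of 18 called and 3 higher adjusted over the list alone (median 0.253, adjusted p = 0.00578, and adjusted p = 0.227 with an estimated correlation); Ptcra had 8 counts in all libraries together and Rag1 had 0. All 20 glycolysis genes had a negative log2 fold change, with 0 called over all genes and 1 lower adjusted over the list alone (median -0.28, adjusted p = 5.26e-08, and adjusted p = 0.0487 with an estimated correlation). Ldha stood at -0.36 (adjusted p = 0.8) and the glucose transporter gene Slc2a3 at -0.73 (adjusted p = 0.178). Unfolded protein and integrated stress response genes had 0 of 32 called and 2 lower adjusted over the list alone (median -0.107, adjusted p = 0.000986, and adjusted p = 0.122 with an estimated correlation), with the cystine transporter gene Slc7a11 at -1.67 (adjusted p = 0.0608). Heat shock genes had 0 of 10 called by either count (median -0.201, adjusted p = 0.0194, and adjusted p = 0.248 with an estimated correlation). The 8 list calls named so far held in each of the 8 fits that left out 1 library.

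The other 6 list calls at 4 h were each lost in at least 1 such fit, and none of their members was called over all genes. Integrin, chemokine receptor and adhesion genes had 3 of 29 higher adjusted over the list alone (median 0.177, adjusted p = 0.0149, and adjusted p = 0.333 with an estimated correlation). Their call was lost without replicate 2 of GFP at 4 h (adjusted p = 0.172). In the other 5 lists, 0 members were called adjusted over the list alone. Myeloid and macrophage markers had 10 members tested (median 0.557, adjusted p = 0.0186, and adjusted p = 0.368 with an estimated correlation). Their adjusted p was 0.0853 without replicate 2 of GFP at 4 h, 0.307 without replicate 2 of E47-ER at 4 h, and 0.123 and 0.137 without replicate 1 and 2 of GFP at 16 h. Immediate early and AP-1 genes had 28 members tested (median -0.252, adjusted p = 0.0262, and adjusted p = 0.356 with an estimated correlation). Their adjusted p was 0.179 without replicate 2 of GFP and 0.242 without replicate 1 of E47-ER at 4 h.

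Mitochondrially encoded genes had 14 members tested at 4 h (median -0.233, adjusted p = 0.0149, and adjusted p = 0.5 with an estimated correlation). Their adjusted p was 0.179 without replicate 2 of GFP and 0.446 without replicate 2 of E47-ER at 4 h. Ribosome biogenesis and MYC target genes had 32 members tested (median -0.126, adjusted p = 0.00578, and adjusted p = 0.541 with an estimated correlation), and without replicate 1 of GFP at 4 h their adjusted p was 0.411. Interferon response genes had 29 members tested (mean -0.474, adjusted p = 0.00493, and adjusted p = 0.693 with an estimated correlation). Without replicate 1 of GFP at 4 h their mean was 0.0727, on the other side of 0 (adjusted p = 0.436).

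The number of called genes at 4 h was 1 without either GFP library at 4 h, 3 and 4 without replicate 1 and 2 of E47-ER at 4 h, 6 without either E47-ER library at 16 h, and 619 and 612 (374 higher) without replicate 1 and 2 of GFP at 16 h. Esr1 was called in all 8 of these fits, Cdk20 in 6, and Cbfa2t3 and Snai3 in 4. Ctsl, Gal, Cd27, Spsb1, Crispld2, Sema6d, St8sia1, Trbc1, Trbc2, Ltb, Nlrp3 and Zbtb32 were called in 2, those without either GFP library at 16 h. Each of these genes kept its direction in all 8 fits. Log2 fold changes ran from 2.064 to 2.12 for Spsb1, 1.491 to 1.562 for Trbc2 and -1.166 to -1.031 for Nlrp3. Wider ranges were 7.2 to 8.18 for Gal, 2.847 to 3.36 for Ctsl and 0.9286 to 1.395 for Ltb. The 39 genes were all among the 612, and DESeq2 with all 8 libraries called 121 genes, 104 of them higher.

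**Figure D3:**
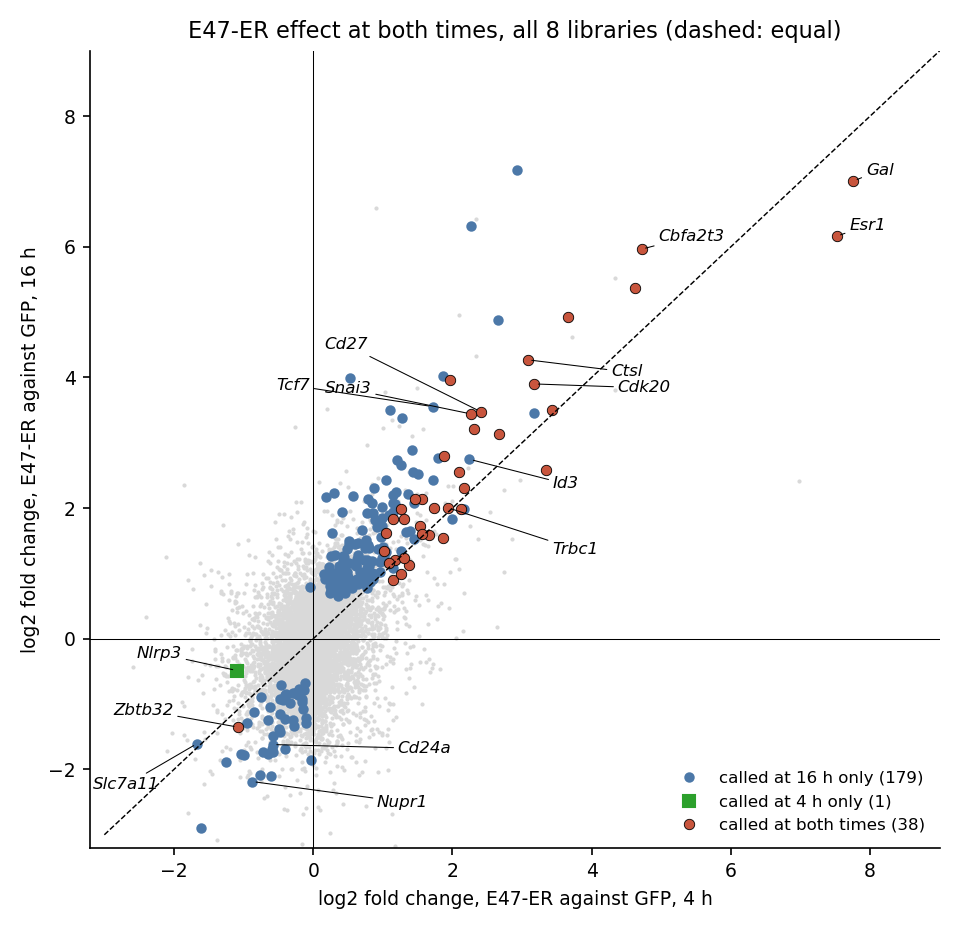
Log2 fold change of E47-ER over GFP at 4 h (x axis) against 16 h (y axis), 1 point per gene, with genes called at 16 h only (179), at 4 h only (1) and at both times (38) in separate colours and named genes marked. The genes called at both times lie on the same side of 0 at 4 and 16 h; 4 genes without a call lie outside the axes.

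At 16 h, 171 genes were higher and 46 were lower with E47-ER. The higher genes included Esr1 and Tcf3, whose reads include the construct. Ctsl stood at 798 ± 31.1 CPM against 41.8 ± 21.1 in GFP cells (SD, n = 2; log2 fold change 4.27, SE 0.352, adjusted p = 0.00228), Cdk20 at 23.3 ± 1.92 against 1.54 ± 0.104 (3.90, SE 0.223, adjusted p = 0.000557) and Cbfa2t3 at 14.3 ± 2.002 against 0.201 ± 0.0958 (5.96, SE 0.365, adjusted p = 0.000557). Gal reached 40.8 ± 5.25 CPM against 0.268 ± 0.191 (7.005, SE 0.447, adjusted p = 0.00179). The GFP levels of Cbfa2t3 and Gal rest on few counts, since 3 counts over the GFP group at 16 h would give 0.134 CPM. Tcf7, the gene of the T cell and ILC transcription factor TCF-1 (ENSMUSG00000000782; chromosome 11, 52252371 to 52283014), rose from 1.44 ± 0.529 to 17.96 ± 1.79 CPM (3.55, SE 0.351, adjusted p = 0.00414). Higher genes with a log2 fold change above 2.5 also included Snai3 (3.44, adjusted p = 0.000557), Cd27 (3.47, adjusted p = 0.00414), Crispld2 (3.21, adjusted p = 0.00286), Lrrc32 (2.80, adjusted p = 0.00179), Id3 (2.75, adjusted p = 0.0171) and the immunoglobulin gene Ighm (2.65, adjusted p = 0.0305). The last 2 were called in 2 of the 8 fits that each left out 1 library, and their log2 fold changes ran from 2.285 to 3.63 (Id3) and from 2.02 to 3.45 (Ighm) over the 8.

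The lower genes at 16 h were led by Nupr1, a stress-induced transcriptional regulator (ENSMUSG00000030717; chromosome 7, 126623249 to 126630861), at 61.5 ± 3.53 against 280 ± 119 CPM (log2 fold change -2.19, SE 0.268, adjusted p = 0.0102). Cd24a, a surface glycoprotein gene (chromosome 10, 43578284 to 43584265), stood at 45.2 ± 5.14 against 139 ± 23.5 CPM (-1.62, SE 0.163, adjusted p = 0.00422), and Zbtb32 (chromosome 7, 30589681 to 30598909) at 19.3 ± 2.49 against 49.3 ± 0.777 CPM (-1.35, SE 0.146, adjusted p = 0.00581). Also lower were Phlda1 (-1.77, adjusted p = 0.0329), the protease inhibitor gene Slpi (-1.76, adjusted p = 0.0271), Ankrd36 (-1.69, adjusted p = 0.0376), the ubiquitin hydrolase gene Uchl1 (-1.68, adjusted p = 0.0467), Clec2l (-1.49, adjusted p = 0.0116), Selenom (-1.42, adjusted p = 0.0422) and the tRNA methyltransferase gene Mettl1 (-1.34, adjusted p = 0.0196). Of these 7, Clec2l was called in 6 of the 8 fits that each left out 1 library and the other 6 in 2 of 8, those without either GFP library at 16 h. Without replicate 2 of GFP at 16 h the values were smaller: Phlda1 -1.18, Slpi -1.23, Ankrd36 -1.27, Uchl1 -1.09, Clec2l -1.29, Selenom -0.919 and Mettl1 -1.14 (adjusted p of 0.000814 or less), and Nupr1 had -1.68 (adjusted p = 2.08e-10). Nlrp3, lower at 4 h, had -0.49 at 16 h (adjusted p = 0.136). The difference between the times did not pass (0.61, SE 0.209, adjusted p = 0.699).

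Of the 33 lists, 17 were called at 16 h with the preset correlation, 9 higher and 8 lower, and none of the 17 with an estimated correlation. The E protein and Id network had 3 of 8 members higher, Cbfa2t3, Id3 and Tcf3, and 7 higher and 1 lower adjusted over the list alone (median 1.11, adjusted p = 1.28e-10, and adjusted p = 0.0714 with an estimated correlation). The rise of Tcf3 includes the construct, and the list was not tested without Tcf3 and Id1. T lineage genes had 5 of 27 higher, among them Tcf7, Cd27, Trbc2 (1.72, 31.3 to 103 CPM, adjusted p = 0.00458) and the Src family kinase gene Lck (1.44, adjusted p = 0.00646). Adjusted over the list alone 9 were higher (median 0.282, adjusted p = 9.94e-07, and adjusted p = 0.196 with an estimated correlation), while Bcl11b, a T cell and ILC2 transcription factor, had 0.47 (adjusted p = 0.132). Integrin, chemokine receptor and adhesion genes had 4 of 29 higher, Ccr8 (1.38, adjusted p = 0.00635), Itgae (1.07, adjusted p = 0.0271), Ccr9 (2.74, adjusted p = 0.0312) and Ccr2 (0.84, adjusted p = 0.0422). There were 9 higher and 1 lower adjusted over the list alone (median 0.272, adjusted p = 0.000813, and adjusted p = 0.197 with an estimated correlation). Over the 8 fits that each left out 1 library Ccr8 was called in 6 and Itgae, Ccr9 and Ccr2 in 2 (highest adjusted p of 0.314, 0.266 and 0.38), and these 3 were lost with a replicate block within each time (adjusted p of 0.121, 0.121 and 0.151). Ccr9 overlaps Lztfl1 and Itgae overlaps Haspin, so reads of these may be shared. ILC2 identity genes had 4 of 38 higher, Tcf7, Ccr8, Rora (1.004, SE 0.134, 76.98 to 154 CPM, adjusted p = 0.0139) and Ccr9. There were 11 higher and 1 lower adjusted over the list alone (median 0.127, adjusted p = 0.00497, and adjusted p = 0.197 with an estimated correlation). Gata3 had -0.43 (adjusted p = 0.249), Il1rl1 -0.08 (0.757), Il17rb 1.01 (0.0598), Klrg1 -0.73 (0.182), Icos 0.07 (0.76), Il7r -0.09 (0.675) and Il2ra -0.45 (0.142). When replicate 2 of GFP at 16 h was left out, Gata3 had -0.0803 (adjusted p = 0.719) and Klrg1 -0.298 (0.664), while Il17rb (0.896, adjusted p = 0.00763) and Il2ra (-0.53, adjusted p = 0.000814) passed.

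Type 2 cytokines and secreted effectors fell as a list at 16 h, with a negative log2 fold change in 18 of 25 members. Over all genes 1 was higher, Tnf (1.33, adjusted p = 0.0172), and 0 were lower, with 2 higher and 11 lower adjusted over the list alone (median -0.506, adjusted p = 0.00958, and adjusted p = 0.469 with an estimated correlation). Il13 stood at 5722 ± 152 against 8958 ± 1263 CPM (-0.65, SE 0.153, adjusted p = 0.0898). Il5 stood at 3607 ± 42.8 against 6418 ± 1908 CPM (-0.83, SE 0.22, adjusted p = 0.114), Il4 at -0.78 (adjusted p = 0.149) and Areg at -0.96 (adjusted p = 0.117). Without replicate 2 of GFP at 16 h the list median was -0.219 (adjusted p = 0.00549, and adjusted p = 0.276 with an estimated correlation). At 4 h Il13 and Il5 did not pass with all 8 libraries (-0.36 and -0.47, adjusted p = 0.838 and 0.916). The fit without replicate 2 of GFP at 16 h called both at 4 h (-0.36 and -0.46, adjusted p = 0.0059 and 0.00337) and at 16 h (-0.50 and -0.50, adjusted p = 0.000834 and 0.00531). Of the other 7 fits that left out 1 library, only that without replicate 1 of GFP at 16 h did so. In the fit without replicate 2 of GFP at 16 h, Il4 had -0.28 (adjusted p = 0.15) and Areg -0.54 (adjusted p = 0.135) at 16 h. It also called Id2 higher at both times (0.87 and 1.12).

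Ribosome biogenesis and MYC target genes had 4 of 32 members lower at 16 h. These were Srm, a polyamine synthesis gene (-0.96, adjusted p = 0.024), Nop16 (-0.86, adjusted p = 0.0299), the fibrillarin gene Fbl (-0.79, adjusted p = 0.0387) and Dkc1 (-0.91, adjusted p = 0.0407), which overlaps Mpp1. Each of the 4 was called in 2 of the 8 fits without 1 library, and none with library totals only (adjusted p of 0.0738 to 0.126) or with a replicate block within each time (0.0812 to 0.16). There were 20 lower adjusted over the list alone (median -0.532, adjusted p = 2.68e-11, and adjusted p = 0.207 with an estimated correlation). Without replicate 2 of GFP at 16 h, 27 of the 32 were lower (median -0.564, adjusted p = 2.26e-25, and adjusted p = 0.246 with an estimated correlation). Cytosolic ribosomal protein genes had 0 of 44 called over all genes and 41 lower adjusted over the list alone (median -0.849, adjusted p = 1.63e-15, and adjusted p = 0.447 with an estimated correlation). These short transcripts stood, on average, 1.07 higher on the log2 scale in replicate 2 of GFP at 16 h than in GFP cells at 4 h, against 0.109 in replicate 1, and without replicate 2 the median was -0.322 with 23 lower (adjusted p = 3.66e-16, and adjusted p = 0.331 with an estimated correlation). Nuclear genes of the respiratory chain had 0 of 30 called by either count (median -0.526, adjusted p = 4.52e-05, and adjusted p = 0.447 with an estimated correlation), and without that library their median was -0.129 (adjusted p = 0.0095, and adjusted p = 0.602 with an estimated correlation). Nuclear and non-polyadenylated RNAs had 0 of 13 called and 8 lower adjusted over the list alone (median -0.93, adjusted p = 2.47e-05, and adjusted p = 0.347 with an estimated correlation). Without that library their median was -0.579 (adjusted p = 0.000571, and adjusted p = 0.246 with an estimated correlation).

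Of the 17 list calls at 16 h, those of the E protein and Id network, T lineage genes, integrin and adhesion genes, type 2 cytokines, ribosome biogenesis genes, ribosomal protein genes, respiratory chain genes and nuclear RNAs held in each fit without 1 library. The other 9 were lost in at least 1. Without replicate 1 of GFP at 16 h the adjusted p of ILC2 identity genes was 0.231. E protein targets had 2 of 18 members higher, Ccr9 and the Ras activator gene Rasgrp1 (1.09, adjusted p = 0.00581), and 4 higher adjusted over the list alone. The median was 0.164 (adjusted p = 0.00944, adjusted p = 0.207 with an estimated correlation, and 0.108 without replicate 1 of GFP at 16 h). Of the ILC3 and type 17 genes 1 of 15 was higher, Ltb (1.83, adjusted p = 0.00286), and 3 adjusted over the list alone. Their median was 0.265 (adjusted p = 0.011, adjusted p = 0.447 with an estimated correlation, and 0.53 without replicate 1 of GFP at 16 h). Glycolysis genes had 0 of 20 called and 10 lower adjusted over the list alone. Their median was -0.378 (adjusted p = 0.00153, adjusted p = 0.196 with an estimated correlation, and 0.0956 without replicate 1 of GFP at 16 h).

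Unfolded protein and integrated stress response genes had 1 of 32 members lower at 16 h, Slc7a11 (-1.60, adjusted p = 0.0271), and 1 higher and 5 lower adjusted over the list alone. Their median was -0.23 (adjusted p = 0.011, and adjusted p = 0.197 with an estimated correlation). The adjusted p was 0.127 without replicate 1 of GFP and 0.0557 without replicate 2 of E47-ER at 16 h. Heat shock genes had 0 of 10 called and 3 lower adjusted over the list alone (median -0.258, adjusted p = 0.0195, and adjusted p = 0.207 with an estimated correlation). In the same 2 fits their adjusted p was 0.192 and 0.0637. Thymic epithelial and stromal markers had 1 of 5 higher by either count, the adhesion gene Epcam (1.56, adjusted p = 0.0285). Their median was 0.371 (adjusted p = 0.0366, and adjusted p = 0.241 with an estimated correlation), with 0.168 and 0.0715 as the adjusted p in the same 2 fits.

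G2 and M phase genes had 0 of 34 members called at 16 h by either count (median 0.32, adjusted p = 0.00958, and adjusted p = 0.589 with an estimated correlation). Their mean log2 fold change was 0.234, and ran from 0.106 to 0.478 over the 8 fits that each left out 1 library. Their adjusted p was 0.0757 without replicate 2 of GFP and 0.135 without replicate 1 of E47-ER at 16 h. IL-2, IL-7, IL-25 and IL-33 receptor pathway genes had 0 of 27 called and 2 higher adjusted over the list alone (median 0.173, adjusted p = 0.0384, and adjusted p = 0.589 with an estimated correlation). Their mean was 0.184, and ran from 0.0815 to 0.326 over the same 8 fits. Their adjusted p was 0.271 without replicate 2 of GFP and 0.082 without replicate 2 of E47-ER at 16 h. The 12 lists called at neither time held genes of ILC1 and NK cells, inhibitory receptors, cytokine feedback, quiescence, S phase, G1 cyclins, apoptosis, p53 targets, cholesterol synthesis, fatty acids, mast cells and sex-linked transcripts. Their adjusted p was 0.0829 or more at 4 h and 0.0777 or more at 16 h. The fit without replicate 2 of GFP at 16 h called 6 of them higher: p53 targets at 4 h (adjusted p = 0.0426), and at 16 h genes of ILC1 and NK cells (0.0249), inhibitory receptors (0.0203), cytokine feedback (0.0303), apoptosis (0.0426) and cholesterol synthesis (0.0304). None of the 6 was called in that fit with an estimated correlation (adjusted p of 0.357 or more).

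The count at 16 h was 63 without either GFP library at 4 h, 62 without either E47-ER library at 4 h, 7022 and 1262 (621 higher) without replicate 1 and 2 of GFP at 16 h, and 26 and 15 without replicate 1 and 2 of E47-ER at 16 h. Cbfa2t3, Cdk20, Crispld2, Ctsl, Esr1, Gal, Lrrc32 and Snai3 were called in all 8 of these fits, Rora and Tnf in 4, and Tcf3, Epcam and Slc7a11 in 2. The 1262 held 216 of the 217 genes in the same direction, whereas DESeq2 with all 8 libraries called 1053 genes, 437 of them higher, and shared 204.

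**Figure D4:**
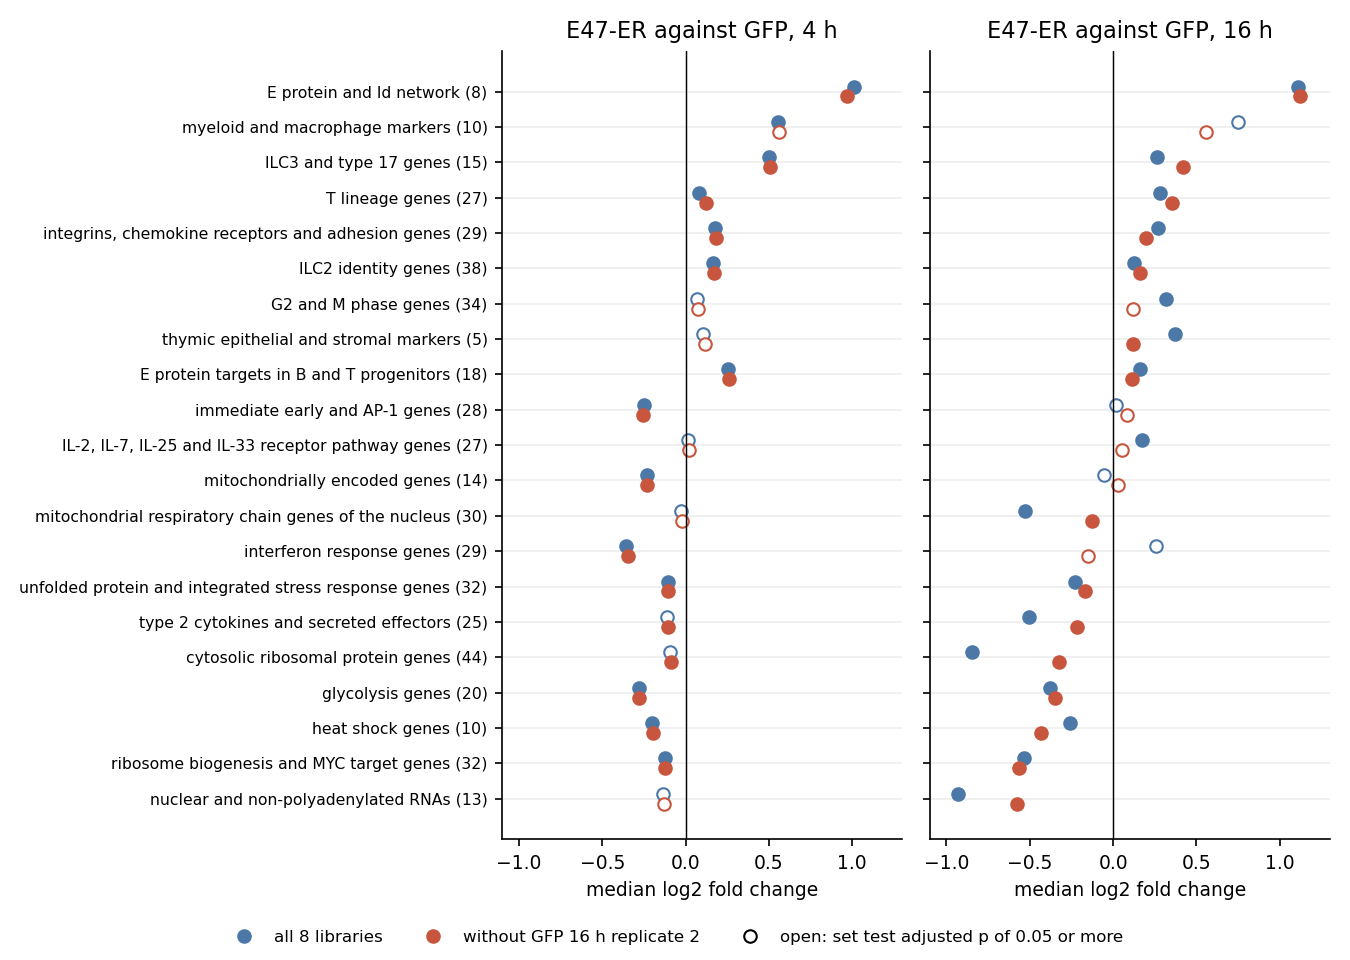
Median log2 fold change of E47-ER over GFP (x axis) at 4 h and 16 h for the 21 gene lists called at either time (y axis), with all 8 libraries (blue) and without replicate 2 of GFP at 16 h (red); open symbols have an adjusted p of 0.05 or more by camera. Cytosolic ribosomal protein genes at 16 h move from -0.849 with all libraries to -0.322 without that library.

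Of the 37 genes higher at 4 h, 37 were also higher at 16 h, where independent calls would give 0.464. Of the 2 lower genes, 1 was lower at 16 h, Zbtb32 (0.00674 expected). The 4 h and 16 h comparisons share no library, but both use the same estimate of spread for each gene, so their calls are not fully independent. Genes are not independent replicates either. Esr1, whose reads include the construct, is among the shared genes. It is the only shared gene left without either GFP library at 4 h. Of the 37 genes, 27 had a larger log2 fold change at 16 h, with medians of 1.88 at 4 h and 2.13 at 16 h. Without replicate 2 of GFP at 16 h, 261 higher genes (16.4 expected) and 137 lower genes (10.8 expected) were shared, and no gene was called in opposite directions. The shared count of 38 fell to 1 without either GFP library at 4 h, 3 and 4 without replicate 1 and 2 of E47-ER at 4 h and 6 without either E47-ER library at 16 h, and rose to 410 and 398 without replicate 1 and 2 of GFP at 16 h.

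When the E47-ER effect at 16 h was tested against that at 4 h, 0 genes passed by edgeR's quasi-likelihood test and 0 by DESeq2, with 671 genes at an unadjusted p under 0.05. The smallest p values among expressed genes were those of Cd24a (difference of log2 fold change -1.04, SE 0.225), Slc27a1 (0.83, SE 0.192), Lgals9 (0.75, SE 0.174), Snai3 (1.18, SE 0.287) and Mettl1 (-1.06, SE 0.272), each with adjusted p = 0.699. Without replicate 2 of GFP at 16 h, 6 genes passed. The receptor phosphatase gene Ptprs (1.63, SE 0.182, adjusted p = 0.000117), Ctsl (1.80, SE 0.196, adjusted p = 0.000905) and the galectin-9 gene Lgals9 (0.76, SE 0.128, adjusted p = 0.0137) had a higher effect at 16 h. Cd24a (-0.87, SE 0.145) and Nupr1 (-0.80, SE 0.135), each with adjusted p = 0.0137, and the ribosomal protein pseudogene Rpl17-ps4 (-5.01, adjusted p = 0.000402), which was named only after its values were seen, had a lower one. Leaving out replicate 1 of GFP at 16 h instead gave 5124 genes, and the other 6 fits gave 0. By list, ribosome biogenesis genes differed between the times (median difference -0.379, camera adjusted p = 2.61e-08, and adjusted p = 0.741 with an estimated correlation), and this held in each fit without 1 library.

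Over time in GFP cells, which gives the background of 16 against 4 h in culture with 4-hydroxytamoxifen, 0 genes passed by edgeR's quasi-likelihood test and 0 by DESeq2, with 1238 at an unadjusted p under 0.05. The genes with the smallest p included the histone genes Hist1h2ao (log2 fold change 0.73, SE 0.158) and Hist1h2ap (0.85, SE 0.213), the prefoldin genes Pfdn2 (0.71, SE 0.178) and Pfdn6 (0.72, SE 0.191), and Zfp790 (-0.61, SE 0.162) and Washc4 (-0.54, SE 0.147), each with adjusted p = 0.5. When replicate 2 of GFP at 16 h was left out 1 gene passed, Rpl17-ps4 (5.63, SE 0.27, adjusted p = 6.28e-12), and without replicate 1 of GFP at 16 h 6034 did. The rise of Rpl17-ps4 rests on 1 GFP library at 16 h. The lower E47-ER effect at 16 h given for this gene above uses the same library and largely mirrors that rise in GFP cells. With all 8 libraries, higher lists were cytosolic ribosomal protein genes (median 0.673, adjusted p = 1.52e-16), respiratory chain genes (0.537, adjusted p = 1.65e-06), nuclear RNAs (0.573, adjusted p = 7.49e-05), ribosome biogenesis genes (0.143, adjusted p = 0.0188) and type 2 cytokines (0.294, adjusted p = 0.0298). Cytokine receptor pathway genes (-0.149, adjusted p = 0.00296) and integrin and adhesion genes (-0.204, adjusted p = 0.0481) were lower. None of the 7 was called with an estimated correlation (adjusted p of 0.826 to 0.871). The fit without replicate 2 of GFP at 16 h called 18 lists, 5 of the 7 and 13 others, and none of the 18 with an estimated correlation (adjusted p of 0.521 to 0.596). In it the ribosomal protein median was 0.117 (adjusted p = 6.12e-06, and adjusted p = 0.527 with an estimated correlation). The respiratory chain median was 0.0568 (adjusted p = 0.032, and adjusted p = 0.581 with an estimated correlation). Of the 13 others, 4 were higher: S phase (median 0.186, 33 of 34 members positive, adjusted p = 8.27e-09), G2 and M phase (0.166, 33 of 34, adjusted p = 6.8e-08), heat shock (0.131, adjusted p = 0.0121) and interferon response genes (0.369, adjusted p = 0.0111). The 9 lower ones included cholesterol synthesis (-0.192, adjusted p = 5.33e-06) and ILC2 identity genes (-0.0774, adjusted p = 0.0137). The calls of type 2 cytokines (median -0.0321, adjusted p = 0.681) and nuclear RNAs (0.232, adjusted p = 0.0578) were lost without that library.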

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

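Of the tests weighed here, those of transcript length, of a swap, of the ribosome lists without replicate 2 of GFP at 16 h and of T cells were chosen after the result was seen, while thinning and the correction for length and GC content were written first.

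Replicate 2 of GFP at 16 h stood apart from the other libraries. Lower sequencing depth is argued against: with every library thinned to its total, its mean correlation with the others was 0.955, against 0.978 or more for the rest. A swap with an E47-ER library is argued against by its Esr1 level of 0.93 CPM and by the absence of a partner among the E47-ER libraries. Its deviation from the other GFP libraries had a Spearman correlation across genes with transcript length of -0.447. For the other GFP libraries, whose reference left out replicate 2 of GFP at 16 h, it was 0.169, -0.0332 and -0.156. Recovery that depends on transcript length would give such a trend, as part of the cause. Length and GC content together held 21.3% of the variance of the deviation, so the rest stays open, and no biological explanation was tested.

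Ribosome genes were lower with E47-ER at 16 h. An excess of short transcripts in replicate 2 of GFP is argued against as the whole cause. Without that library the mean log2 fold change stayed negative, at -0.547 for ribosome biogenesis genes and -0.325 for cytosolic ribosomal protein genes. Neither list was called in that fit with an estimated correlation. With all libraries the mean for ribosomal protein genes was -0.887, so the size of that change depends on the library. After the trend with length and GC content was removed from the remaining libraries, the means hardly changed, at -0.582 and -0.314, which argues against that trend. Genes of these lists moved together: their estimated inter-gene correlation at 16 h with all 8 libraries was 0.245 and 0.938. The preset of 0.01 is far below that, and the means after removal were not tested with an estimated correlation. For ribosome biogenesis genes, GFP replicates 1 and 2 at 16 h stood on average 0.18 and 0.0968 above GFP cells at 4 h on the log2 scale. E47-ER replicates 1 and 2 at 16 h stood at -0.283 and -0.437, which argues against a deviation of 1 GFP library alone for this list. For ribosomal protein genes such a deviation stays open. The labels do not say whether replicates are separate cultures, so a culture difference stays open for both lists. A response of ribosome genes to E47 activity remains a hypothesis.

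T lineage genes were higher with E47-ER by camera with the preset correlation, with 3 of 27 members called at 4 h and 5 at 16 h, but not with an estimated correlation (adjusted p = 0.0721 and 0.196). Alpha-beta T cells among the E47-ER cells would bring CD3 and T cell receptor alpha transcripts with those of the beta chain. At 16 h Trbc2 exceeded the highest of Cd3d, Cd3e, Cd3g, Cd247 and Trac by 1.15 on the log2 scale (SE 0.334). Added cells would give a small fold change where GFP cells already held the transcript, as for Cd3e (27 CPM) and Cd247 (55.6 CPM). In CPM, Trbc2 rose by 71.2, against 0.925 for Trac, 9.14 for Cd3e, 8.59 for Cd247, 1.44 for Cd3g and -0.754 for Cd3d. This argues against alpha-beta T cells as the whole source. Cd3e and Cd247, the most abundant of these 5 genes, had log2 fold changes of 0.42 (adjusted p = 0.147) and 0.21 (adjusted p = 0.361), and were called higher without replicate 2 of GFP at 16 h (0.468 and 0.361, adjusted p = 0.0318 and 0.0485). Gamma-delta T cells would bring CD3 transcripts as well. Trdc and Tcrg-C1 were also higher at 16 h, by 96.4 and 51.8 CPM. The rises of Cd3e, Cd247, Cd3g and Cd3d were smaller, at 9.14 CPM or less. This argues against gamma-delta T cells as the whole source of the Trdc and Tcrg-C1 rises, while a share from them stays open. A response of the T lineage genes within ILC2 remains a hypothesis, and reads that the deposited counts assign to the wrong gene were not tested.

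By camera the E47-ER effect differed between the times for 9 lists, as the mean difference of log2 fold change, 16 h minus 4 h. It was 0.187 for T lineage genes (adjusted p = 0.0309), -0.384 for ribosome biogenesis genes (2.61e-08), -0.792 for cytosolic ribosomal protein genes (9.91e-16), -0.492 for respiratory chain genes (3.26e-05) and -0.793 for nuclear RNAs (2.13e-05). When replicate 2 of GFP at 16 h was left out, the last 3 were -0.233 (adjusted p = 1.56e-13), -0.0946 (0.0254) and -0.449 (0.00102), and not called with an estimated correlation (adjusted p of 0.579 to 0.616). It was -0.354 for type 2 cytokines, 0.175 for receptor pathway genes, 0.174 for G2 and M phase genes (adjusted p = 0.0307 each) and 0.579 for interferon response genes (adjusted p = 0.00539), and these 4 were lost without replicate 2 of GFP at 16 h (0.164, 0.196, 0.352 and 0.37). Type 2 cytokines were also lost without replicate 2 of GFP or of E47-ER at 4 h or replicate 1 of E47-ER at 16 h. Receptor pathway genes were also lost without replicate 1 of GFP at 4 h or replicate 2 of E47-ER at 16 h. G2 and M phase genes were also lost without replicate 1 of GFP or 2 of E47-ER at 4 h or replicate 1 of E47-ER at 16 h, and interferon response genes without replicate 1 of GFP at 4 h or of E47-ER at 16 h. T lineage genes were lost without replicate 1 of GFP at 4 h (0.0688), of E47-ER at 4 h (0.13) or of GFP at 16 h (0.647), or replicate 2 of E47-ER at 16 h (0.14). None of the 9 was called with an estimated correlation (adjusted p of 0.741 to 0.747). The fit without replicate 2 of GFP at 16 h called 6 further lists, all with a positive mean difference and none with an estimated correlation (adjusted p of 0.579 to 0.597): inhibitory receptors (0.203, adjusted p = 0.0169), cytokine feedback (0.148, 0.00146), immediate early (0.403, 0.00576), cholesterol synthesis (0.231, 7.08e-05), fatty acid (0.156, 0.0125) and mitochondrially encoded genes (0.251, 0.00274).

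For 3 genes, both libraries of E47-ER lay on 1 side of GFP at 4 h and on the other at 16 h, and the difference of log2 fold change was -0.672 for Hist1h2ap, -0.785 for Pfdn6 and 0.964 for Zfp101. This was not tested as such, and in the test of the difference across genes each had an adjusted p of 0.699. They were named for a small p between the times in GFP cells. Such a shift in GFP can by itself place E47-ER on opposite sides. The pattern may therefore follow from how these genes were chosen, and is no evidence of an E47-ER effect.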

How the results depend on the processing

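The fit by voom with quality weights was chosen after the data were seen. Genes called at 4 h (39), at 16 h (217) and at both times (38) became 121, 1053 and 108 with DESeq2, 165, 1816 and 139 with no filter on low counts, 68, 500 and 65 at an adjusted p under 0.10, and 5, 47 and 5 under 0.01. They became 442, 6 and 6 with only the 4 libraries of that time, 11, 54 and 11 with a replicate block within each time, and 28, 195 and 28 with it across times. The replicate numbers were not seen to pair libraries: correlations of replicate deviations between groups were 0.0237, 0.0281, 0.202, 0.0298, 0.0404 and -0.0901. Library totals only gave 19 at 4 h and 19 at both times, and moved the median of all genes by 0.121 at 16 h. Voom gave 401 at 4 h and 52 at 16 h, with weights of 0.202 and 0.228 for the GFP libraries at 16 h, since it could not tell which of the 2 stood apart. With no filter, 53 genes differed between times and 305 over time in GFP cells, and 15 lists differed between times. Leaving out 1 library gave 1 to 619 genes at 4 h, 15 to 7022 at 16 h, 0 to 5124 for the difference between times, 0 to 6034 over time in GFP cells and 1 to 410 at both times. It gave 10 to 16 lists at 4 h, 11 to 20 at 16 h and 7 to 11 for the difference between times. The mean of interferon response genes at 4 h ran from -0.825 to 0.0727, with the sign turned without replicate 1 of GFP at 4 h. Lists called at 4 h, at 16 h and for the difference were 2, 0 and 0 with an estimated correlation and 7, 10 and 0 with fry. The 4 h comparison holds no library of 16 h. Leaving out a library of 16 h therefore changes it only through the shared spread, gene filter and scaling of the fit. Without replicate 2 of GFP at 16 h, the common coefficient of variation between replicates fell from 16.1 to 7.11%. How much each of these contributed was not tested, nor was the cause of the other changes. No called gene among those named changed direction under these alternatives. Of genes without a call, Il1rl1 at 4 h had -0.01074 with no filter, -0.002536 with only the 4 libraries and -0.0005284 with voom, and ran from -0.07607 to 0.07837 without 1 library. With library totals only Il1rl1 had 0.05886 and Il7r 0.03655 at 16 h. Without 1 library Il1rl1 at 16 h ran from -0.1996 to 0.06551, Icos at 16 h from -0.01823 to 0.1876 and Klrg1 at 4 h from -0.5932 to 0.05459. RLE scaling, no robust dispersion and library totals only kept each list call. Genes changed 2-fold were missed about as often as found in simulated data, which limits what a missing call means. Those data held no library that stood apart, so the rate may differ in the real data. The fit with only the 4 libraries of a time was not run for the results across times.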

Other observations

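The tests of neighbouring genes and the choice of antigen receptor genes were made after the results were seen, and the form of the neighbour test was changed 2 times after results were seen.

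Constant genes of several antigen receptors were higher with E47-ER at 16 h. Trdc, of the T cell receptor delta chain, stood at 216 ± 3.46 CPM against 119.65 ± 7.05 (SD, n = 2; log2 fold change 0.85, adjusted p = 0.0189 by edgeR). Tcrg-C1, of the gamma chain, had 0.87 (SE 0.161, adjusted p = 0.0429), and Trbc1 2.01 (SE 0.256, adjusted p = 0.012). Ighm, of the immunoglobulin mu chain, went from 5.17 to 30.4 CPM (2.65, adjusted p = 0.0305). At 4 h, by the same test, Trbc1 passed (1.94, adjusted p = 0.033). Trdc (0.528, adjusted p = 0.278), Tcrg-C1 (0.822, 0.15) and Ighm (1.26, 0.633) did not. For none of these genes did the difference between the times pass (adjusted p of 0.699 or more). Calls of Trdc and Tcrg-C1 were not followed over the 8 fits that each left out 1 library. Other constant genes did not pass: Trac had 0.40 (adjusted p = 0.461), Tcrg-C2 0.396 (0.308) and Tcrg-C4 0.60 (0.136). The recombinase genes Rag1 and Rag2 had 0 counts in the 8 libraries, and the B cell genes Ms4a1, Cd79a and Igkc had 4, 36 and 7 counts in total. Cd79b, of the B cell receptor complex, had 911 counts in total (6.55 to 11.0 CPM in the groups), with a log2 fold change of -0.53 at 16 h (adjusted p = 0.21).

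Higher genes with E47-ER may lie near each other more often than random genes, a hypothesis prompted by Ctsl and Cdk20 (61.4 kb apart on chromosome 13) and Snai3 and Cbfa2t3 (164 kb apart on chromosome 8). It was tested with these 4 genes left out, as the number of higher genes with another higher gene of another family 10 to 500 kb away, against 2000 random gene sets matched on expression. At 4 h, 2 of 33 genes had such a neighbour, within the random range of 0 to 4 (one-sided permutation p = 0.4). At 16 h, 32 of 167 did, within the range of 12 to 37 (permutation p = 0.13). In the fit without replicate 2 of GFP at 16 h, 145 of 369 genes did at 4 h, above the range of 85 to 128 (permutation p = 0.001), and 287 of 617 at 16 h, above the range of 224 to 282 (permutation p = 0.013). The fits with and without that library differ in this, so the question stays open at both times. With the prompting genes included, the counts with all 8 libraries were 6 of 37 at 4 h (permutation p = 0.024) and 36 of 171 at 16 h (permutation p = 0.055), and 4 of those 6 are the prompting genes. With these genes included, members of 1 family allowed and any gap above 0 and under 500 kb, so that overlapping pairs stay out, they were 8 of 37 (random median 0) and 47 of 171 (random median 27). Lower genes lay within the random range: 2 of 46 at 16 h with all 8 libraries (permutation p = 0.63), and without that library 51 of 238 at 4 h (permutation p = 0.39) and 298 of 641 at 16 h (permutation p of 0.048 and 0.06 in 2 draws).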
